A study of Saccharomyces cerevisiae with 203 samples.

How the data were processed

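Genomic DNA of budding yeast, Saccharomyces cerevisiae, was compared by 2-colour hybridisation on spotted arrays carrying PCR products of open reading frames (ORFs) and intergenic stretches. Of the 203 arrays, 197 held DNA of a red sector, a coloured part of a colony picked as a strain of its own, against DNA of a reference strain. The other 6 held DNA of cells arrested in G2/M and kept in galactose for 3 h, which report where DNA was replicated a further time within a cycle. Per the labels' protocols, amino-allyl-dUTP was incorporated with Klenow polymerase and the dyes were coupled chemically. Per the design text in the labels, the authors deposited Cy5 over Cy3 ratios scaled to a mean of 1 over all elements of an array. The deposited values themselves were log2 ratios, as their range below 0 showed, and no further scaling of them was described. The scanner, its software, spot filters, background correction and genome build are not given in the sources used here. Signal over background could not be examined, since the deposited tables hold the log2 ratio alone.

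The labelled dyes did not settle the direction of the sector ratios. The design fixed before the data were examined had taken each array's direction from its dyes, with the sign turned where the sector was in Cy3. In sectors of strains named for a rad52 mutation, however, deposited values of RAD52 were positive on all 3 arrays with the sector labelled Cy5 (mean 1.73) and on all 6 with it labelled Cy3 (mean 1.65). TRP1, a common selection marker, had deposited means of −1.14 on 4 and −0.73 on 28 of these arrays. A sector hybridised under both labels, YJL7691, gave r = 0.448 across 7821 features and 0.851 across 758 features of chromosome IV, where genes are not independent replicates. Another such sector, YJL7106, gave r = 0.0913 and settled nothing. On sector arrays the mean of the inverse ratio was 0.999 and that of the ratio 1.08. All sector values were therefore turned to sector over reference by reversing the deposited sign on every array, a departure from the planned design, and the labelled direction was run as an alternative. This direction is likely, not stated by the authors. The 6 profile arrays kept the deposited sign. Among sector arrays of the same labelled dye and reference, no pair correlated below −0.3, and r ranged from −0.134 to 0.979, so that no pair held identical values.

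Each array was centred on its median, with no loess or quantile step, because copy number arrays can carry true shifts. Deposited medians of sector arrays ran from −0.0037 to 1.12, and every value is relative to that centring. Of 14040 features, 11587 were placed on chromosomes through the systematic names in a table of RefSeq genes, 1485 of them on chromosome IV. The placed features comprised 5937 of 6468 ORF and 5586 of 6378 intergenic features. No genome build was named, so positions are given as gene names and distances as numbers of features, where windows had been planned in kb. Values were missing for 37.9% of features on sector arrays and 22.9% on profile arrays, and a sector array held between 715 and 11546 values. The number of arrays limits the precision of every group value. A sector was represented by a single array, that of the sector tables in the labels. The 9 repeat arrays, which the labels tie to figures, entered comparisons only in the alternative that averaged all arrays of a sector, and otherwise served to compare the arrays of a sector. The 188 sectors comprised 36 after re-replication at 567, 24 after re-replication at 1089, 32 controls without re-replication, 24 after phleomycin, 24 dnl4 and 48 rad52 sectors. Nothing in the labels says that sectors of a group came from separate cultures, so p-values measure only the spread between these sectors, which may be technical.

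Gains and losses were called on each array by penalised least-squares segmentation of the placed features. The penalty was 20 times the noise variance, and isolated values over 3 noise SDs from a running median of 5 features were pulled in first. A gain was a run of segments, each of at least 3 features, with a mean log2 of at least 0.4 over at least 10 features, and a loss mirrored it. Gains were whole-chromosome (a share of at least 0.8 of its features), terminal (reaching a share of 0.05 from an end) or internal. The locus, written 567 or 1089 in the labels, was taken as the middle of the plateau at a share of 0.95 or more of the smoothed profile peak, which fell at YDR052C (DBF4) and YDR316W-B. A gain spanned the locus if the locus lay inside it or within 6 features. The pull-in, the minimum segment and the placing of the loci were set after the values had come but before any call was seen, and the other settings and gene lists were fixed before the data were examined. A 95% Clopper-Pearson interval accompanies each share, and it covers sampling of sectors only. Every share is a share of the red sectors picked and gives no rate per cell, colony or culture.

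Shares of sectors were compared by Fisher's exact test, two-sided, in 1 family of 11 tests. For each array, the median log2 ratio was taken over the features within 15 features of the locus on either side. These medians were compared by a two-sided permutation test with 100000 resamples, in 1 family of 6 tests. Where a group had fewer than 10 values, the permutation test was exact. Features were tested with limma, by lmFit and eBayes over all sector groups in 1 fit, with dye orientation and reference strain as covariates and at least 3 values per group, in 5 comparisons at an adjusted threshold of 0.05. All families were adjusted by the Benjamini-Hochberg method. The medians of 8 gene lists, 70 genes in all, were compared by permutation in 30 tests without covariates. The lists were the targeted genes, replication and repair genes of chromosome IV, tandem arrays, strain marker genes, licensing genes, recombination and end-joining genes, mitochondrial genome genes and 2-micron plasmid genes. Of the tandem array genes all 12 were listed with no value on any sector array, none of the 4 plasmid genes was matched to a feature, and 7 of 8 mitochondrial genes were. Neither the tandem array list nor the plasmid list could be tested.

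Genes were named by a rule fixed before the data were examined. It took RAD52 and DNL4, the 3 ORFs nearest to the locus on each side, the 10 ORFs inside called gains of most sectors, and the ORFs at the most frequent ends of gains over the locus. It also took the 5 ORFs off chromosome IV with the lowest adjusted p and a size of at least 0.3, and up to 6 members of each list past the threshold. Genes named from called gains or the lowest adjusted p were picked on the arrays that then tested them, so their differences are no independent evidence. Not every gene that this rule gives is printed. For 1 member of the lists the result is not reported here. For re-replication at 1089 and phleomycin, most-gained ORFs were taken from trend-corrected calls too, a choice made after the data were seen.

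Alternatives fixed before the data were examined changed the gain threshold (0.3, 0.6), minimum length (5, 20), penalty (10, 40), caller, centring, window (6 or 30 features on either side), covariates, arrays and features used. After the data were seen, a trend along all chromosomes was found, and trend-corrected values were added as an alternative. Its template was the median over the 104 arrays of the control, phleomycin and rad52 groups, smoothed over 41 features. Each array was regressed on it over features off chromosome IV, and the fit was subtracted. A form with the phleomycin arrays alone as template was the only other correction tried. The labelled direction, a filter on 12 arrays under 4000 placed features, the test of the window at 1089, and the tests at ends of gains were added in the same way. A planned test of ends at annotated transposable elements was not run, because the annotation used here names none.

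On simulated data with gains of log2 0.6 and no trend, the caller recovered 36 of 36 gains in re-replication at 567 and 23 of 24 in re-replication at 1089. With a trend added, the template scaled by each array's slope, it recovered 7 of 36 and 0 of 24, and after trend correction 36 of 36 and 23 of 24. The correction fits a trend of just that form, so the last 2 counts say nothing of trends that depart from the template. For gains of log2 1 with that trend, it recovered 35 of 36 and 21 of 24 without correction. Limma recovered 86 of 98 features changed by log2 0.5, and 99 of 99 changed by log2 1, for re-replication at 567 against control, with 13 false calls. The corresponding figures for re-replication at 1089 were 63 of 100 and 92 of 99. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, numba 0.67.0 and matplotlib 3.10.9, and R 4.3.3 with limma 3.58.1, were used.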

Results

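Copy number along the yeast genome was measured in 188 red sectors, each on a single array, and re-replication was profiled on 6 further arrays. The study asked whether a failure to limit replication to a single round per cycle starts gene amplification. Strains carried the replication origin ARS317 on chromosome IV, at a site that the labels call 567 or 1089, in a background named MC2A or M. Sectors arose after re-replication at 567 (36 sectors) or at 1089 (24), without re-replication (32 controls at 567), or after phleomycin, a drug that breaks DNA (24). Sectors after re-replication at 567 also came from strains named for rad52 (48), after the gene of a central mediator of homologous recombination, and for dnl4 (24), after the gene of the ligase of end joining. Sector values are given as log2 of sector over reference, a direction that is likely but not stated by the authors. It was taken from the values of RAD52, TRP1 and a sector hybridised under both labels, because the labelled dyes did not settle it. A sector array held values for 715 to 11546 features. RAD52 itself fell by 1.82 ± 0.12 (SE) in rad52 sectors against the other sectors of re-replication at 567 (limma, adjusted p = 4.38e-26), lower in 9 of 9 sectors with a value, while the other 39 rad52 arrays held no value for it. Since RAD52 and TRP1 of rad52 sectors served to choose the direction, their signs there are no independent evidence for it. Of 124 differences of named genes, 71 reversed with the labelled direction. DNL4 had 0 values on the 24 dnl4 arrays, against 29 of 36 arrays of re-replication at 567.

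In cells carrying ARS317 at 567 in the MC2A background, DNA around VMS1, TPI1 and DBF4 was over-represented in G2/M after 3 h of galactose. The smoothed log2 ratio was highest at VMS1 (0.65), and stayed above the middle of that height from iYDR030C to iYDR096W, 138 features. At the same locus the array labelled ars317- gave 0.016 and that of the M background gave 0.061. With ARS317 at 1089 the ratio was highest beside OMS1, at iYDR316W (0.66), and stayed above the middle of that height from YDR287W to iYDR344C, 115 features. The matching controls gave −0.12 and 0.012 there. Each profile is a single array, so none of these heights has a replicate error.

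**Figure D1:**
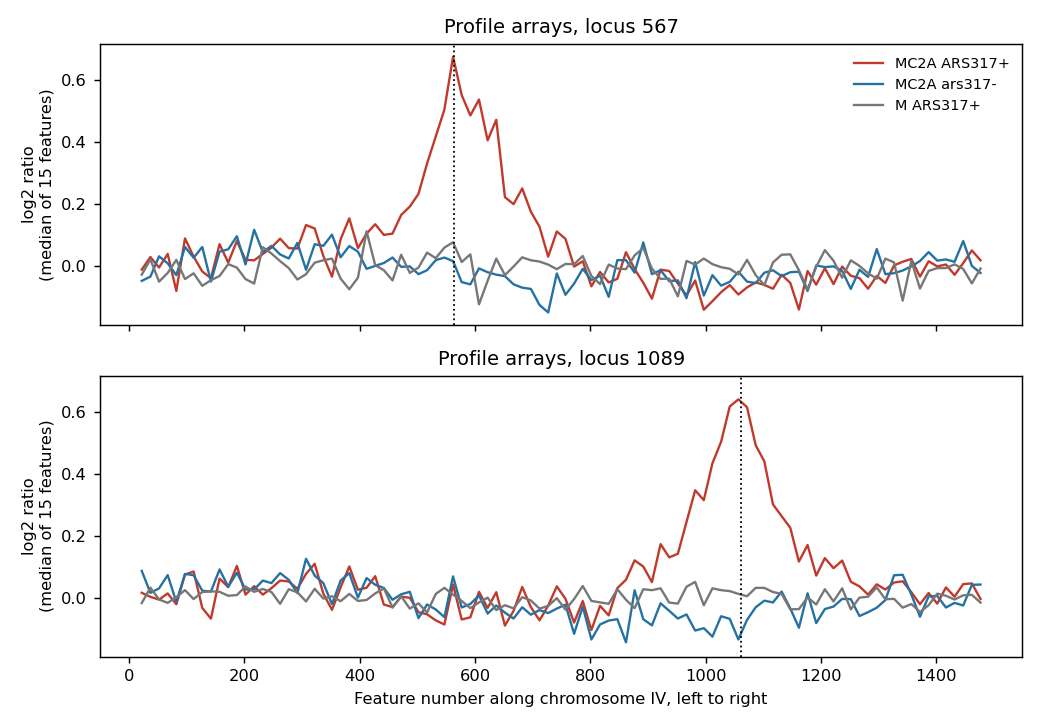
Medians of 15 features along chromosome IV on the profile arrays, as log2 ratio, for strains with ARS317 in the MC2A background and their 2 controls, at 567 above and at 1089 below. The ratio rose around VMS1 in the upper panel and around OMS1 in the lower, where smoothed values reached 0.65 and 0.66.

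After re-replication at 567, the stretch of chromosome IV around DBF4 was gained in most sectors. DBF4 encodes the regulatory subunit of the Cdc7 kinase that fires origins. An internal gain spanning the locus was called in 25 of 36 sectors (69.4%, 95% interval 51.9 to 83.7%), with a mean log2 of 0.60 ± 0.25 (SD, n = 25) and a median length of 86 features. Among controls without re-replication it was called in 3 of 32 (9.38%, 1.98 to 25.0%), with a mean of 0.80 ± 0.35 (SD, n = 3) and a median length of 223 features. The difference of 60.1 percentage points passed Fisher's exact test (adjusted p = 1.04e-06). The median log2 of the window, the features within 15 of the locus on either side, was 0.53 ± 0.40 (SD, n = 36) against −0.14 ± 0.39 (SD, n = 32). It was above the control mean in 33 of 36 sectors (permutation test, adjusted p = 1.2e-05, the smallest it can give in this family). With Cy5 sectors against reference YJL6558 alone, the gain was called in 8 of 9 against 3 of 32 (Fisher's exact test, p = 1.43e-05), and the windows differed by 0.96 (exact permutation test, p = 1.32e-06). With values not centred the gain was called in 15 of 36 against 3 of 32, and a gain threshold of 0.6 ended the call (9 of 36 against 2 of 32, adjusted p = 0.0904). So did the labelled direction (17 of 36 against 7 of 32, adjusted p = 0.0924), with which the window difference was −0.021.

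Genes near the locus carried this gain. DBF4 was higher than in controls by 1.18 ± 0.12 (SE; limma, adjusted p = 9.38e-15) in 28 of 30 sectors. CDC34, a ubiquitin-conjugating enzyme of the cell cycle, was higher by 1.01 ± 0.14 in 24 of 24 (adjusted p = 4.06e-09), and RAD55, which assists recombination, by 1.27 ± 0.12 in 31 of 34 (adjusted p = 5.29e-16). VMS1 (1.14), TPI1 of glycolysis (0.95), DET1 (1.03), PST1 (0.72) and EMC10 (1.22), nearest to the locus, all rose, as did SNF11 of the SWI/SNF complex (0.86), HEM12 of haem synthesis (1.05), the amino acid permease gene BAP3 (1.18), YOS9 (1.12), TVP23 (0.93) and FMP16 (1.02). SNF11 and the genes after it were named for lying in called gains on these arrays, so their rise is no independent evidence. MSH6, a mismatch repair gene at the right edge of many gains, rose by 0.67 ± 0.21 (adjusted p = 0.0346) in 14 of 14 sectors with a value, although 6 controls had one. The fit gave larger differences than the plain means, re-replication before control, for DBF4 (0.66 and −0.098), RAD55 (0.60 and −0.27), EMC10 (0.57 and −0.18) and VMS1 (0.71 and −0.19). It gave a smaller difference than the plain means for MSH6 (0.38 and −0.48). Of the 25 replication and repair genes of chromosome IV, 20 could be tested and these 4 (DBF4, CDC34, RAD55, MSH6) rose, with none lower; adjusted over the list alone, 4 rose and CDC7 fell by 0.22. Trend-corrected, 3 rose over all features and CDC7 fell by 0.24, while MSH6 (0.57, adjusted p = 0.0575) did not pass, nor did it with Cy5 sectors against YJL6558 alone. The median of this list differed by 0.076 (permutation test, adjusted p = 0.132; 23 of 36 sectors above the control mean). Under the labelled direction, with which CDC7 was not run, each of the other genes named here was lower, for example DBF4 (−0.88), RAD55 (−0.81), CDC34 (−0.64) and MSH6 (−0.67), all but SNF11 past the threshold, and the list differed by −0.23 (adjusted p = 5e-05).

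Across the array, 1012 of 11230 features passed limma's threshold, 496 higher and 516 lower. On chromosome IV 145 were higher and 9 lower, and within 60 features of the locus 84 of 101 were higher. The labelled direction instead gave 14 higher and 155 lower on chromosome IV. Lower features included 231 of the 689 tested on chromosome II and 91 of 484 on V. Off chromosome IV, TDA10 (0.66 ± 0.07 SE) and CDC6, which loads the replicative helicase at origins (0.67 ± 0.09), were higher in 32 of 36 and 23 of 24 sectors, with adjusted p of 1.55e-13 and 3.24e-08 (limma). CDC6 had a plain mean of 0.092, against −0.68 in the 10 controls with a value. Before centring it was also below the reference on all 14 phleomycin arrays with a value (mean −0.68). Its means before centring were 0.17 at 1089, 0.066 and 0.13 in rad52 sectors labelled Cy5 and Cy3, and −0.21 in dnl4. The difference of CDC6 thus lay in low values of controls, and is no evidence of its gain after re-replication. SEF1 (0.47) and YCH1 (0.45) were higher, and the checkpoint kinase gene CHK1 fell by 0.62; these 5 reversed with the labelled direction. With values not centred the split was 316 higher and 182 lower. In the fit of these groups alone 172 features passed, and with Cy5 sectors against YJL6558 alone 137, of which 129 were higher and 98 of those lay on chromosome IV.

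**Figure D2:**
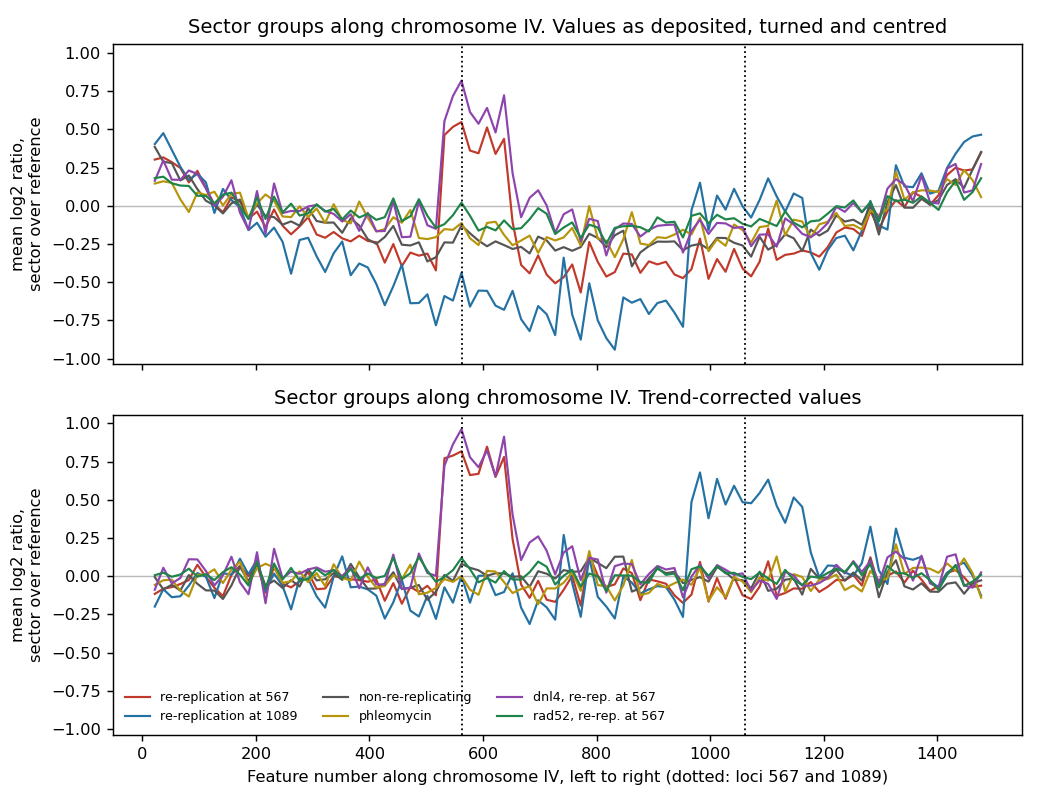
Mean over sectors of the log2 ratio, sector over reference, in bins of 15 features along chromosome IV for the 6 sector groups, with deposited values turned and centred above and trend-corrected values below; dotted lines mark the loci. In both panels re-replication at 567, in otherwise intact and in dnl4 strains, stands above the other groups at the left locus, and re-replication at 1089 rises at the right locus.

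Phleomycin sectors showed no internal gain at DBF4, in 0 of 24 sectors (95% interval 0 to 14.2%), against 25 of 36 after re-replication at 567 (Fisher's exact test, adjusted p = 5.10e-08). The median log2 of the window was −0.15 ± 0.16 (SD, n = 24), and 33 of 36 re-replicating sectors lay above that mean (permutation test, adjusted p = 1.2e-05). Within the shared set of Cy3 sectors against reference YJL6032, the gain was called in 15 of 25 against 0 of 24 (p = 2.90e-06), and the windows were 0.38 and −0.15 (permutation test, p = 1e-05, the smallest it can give). No gain or loss was called anywhere in 11 of 24 phleomycin sectors. This held for 1 of 36 sectors at 567, 0 of 24 at 1089, 1 of 32 controls and 0 of 24 in dnl4. Median gain calls per sector were 1 after phleomycin, 0 in rad52, 2.5 in dnl4, 10 in controls, 11.5 at 567 and 29 at 1089. In that order median slopes on the trend template were 0.62, 0.76, 1.38, 1.73, 2.20 and 3.17, so calls may partly reflect the trend. Trend-corrected, 12 of 24 phleomycin sectors had no call, against 3 of 36 at 567 and 3 of 32 controls. With the labelled direction the window difference was 0.27 and not past the threshold (adjusted p = 0.0864).

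Compared feature by feature with controls, phleomycin sectors differed in many places. The uracil synthesis gene URA3, a common strain marker, fell by 1.01 ± 0.17 (SE; limma, adjusted p = 1.28e-06) and LEU2 by 0.28 ± 0.08 (adjusted p = 0.00476), in 14 of 14 and 19 of 19 sectors. RIB4, of riboflavin synthesis, fell by 0.74 in 20 of 20 sectors, whereas YNL143C (0.63), DNL4 (0.33) and LIF1, the partner of DNL4 (0.27), were higher in 19 of 19, 21 of 21 and 15 of 16. LCL1 (0.38), LGE1 (0.58), LEE1 (0.43) and SUR1 (0.46), a run on chromosome XVI that 2 sectors gained, were higher, LGE1 in 14 of 23 sectors. BAG7 was fitted as higher by 0.62 with plain means of −0.057 and −0.12 (15 of 23 sectors), and MRM2 by 0.39 with −0.021 and −0.030 (13 of 23). In all, 1950 features were higher and 1621 lower, of 11228, and with values not centred 2129 and 682; trend-corrected values gave 1686 in all. Phleomycin sectors and controls shared no combination of dye and reference. The fit therefore leans on the mixture of references within re-replication at 567 and on the mixtures of dyes there and within rad52. Within 60 features of the locus 63 of 101 features were higher in that fit, although the window showed no gain. DBF4 was fitted as higher by 0.61, with plain means of −0.089 in phleomycin sectors and −0.098 in controls. VMS1 (0.56), RAD55 (0.66), PST1 (0.53) and ESC2 (0.46) also passed with plain means above those of controls. The fit opposed the plain means, phleomycin before control, for EMC10 (0.68, with −0.21 and −0.18), DET1 (0.49, with −0.11 and −0.0063), VHT1 (0.61, with −0.23 and −0.18) and PSF1 (0.43, with −0.25 and −0.18). It also did for RAD30 (0.24, with −0.038 and 0.062), ADE2 (0.30, with −0.29 and −0.12) and RTT103 (0.34, with −0.272 and −0.269). Of the chromosome IV replication and repair genes 6 were higher and CDC9 lower, and as many adjusted over the list alone, but trend-corrected only PSF1 was higher (0.25) and none lower, by either count. Trend-corrected, DNL4 (0.16, adjusted p = 0.0755), LIF1 (0.11, adjusted p = 0.348), LEU2 (−0.046, adjusted p = 0.730), ADE2, CDC9, DBF4, VMS1, DET1, PST1, RAD55, ESC2, RAD30 and RTT103 no longer passed. Without dye and reference terms DBF4, VMS1, PST1, RAD55, ESC2, BAG7, MRM2, LGE1 and SUR1 did not pass, with dye alone DET1, PSF1, RTT103, RAD30, LEE1 and SUR1 did not, and with values not centred CDC9 and LEU2 did not. Without dye and reference terms DET1, EMC10, PSF1, RTT103, RAD30, ADE2 and VHT1 turned to lower, and with dye alone ADE2 did. DBF4 (−1.45), VMS1 (−1.38), RAD55 (−1.43), EMC10 (−1.47), DET1 (−1.10), PST1 (−0.91) and YNL143C (−0.025) reversed with the labelled direction, and LEU2, LGE1, ESC2, RTT103, VHT1 and CDC9 no longer passed.

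Gains followed the locus. After re-replication at 1089 an internal gain spanned 567 in 0 of 24 sectors, against 25 of 36 after re-replication at 567 (Fisher's exact test, adjusted p = 5.10e-08), and 15 of 25 against 0 of 24 among Cy3 sectors against YJL6032. Around SUM1 and OMS1 an internal gain spanning 1089 was called in 2 of 24 sectors (8.33%, 1.03 to 27.0%) against 0 of 36, which did not pass (adjusted p = 0.191; 2 of 24 against 0 of 25 among Cy3 sectors against YJL6032, p = 0.235). It passed when arrays were centred on the mode (6 of 24, adjusted p = 0.00493) or averaged over a sector's arrays (4 of 24, adjusted p = 0.0399). Averaging could alter only 2 sectors at 1089, whose repeat arrays both carried the gain while their arrays of the sector tables did not. Trend-corrected values, an alternative chosen after the data were seen, gave it in 17 of 24 (70.8%, 48.9 to 87.4%) against 0 of 36 (adjusted p = 1.64e-09), with a mean log2 of 0.71 ± 0.09 (SD, n = 17). In the values as deposited 15 of the 24 sectors instead had a terminal gain on chromosome IV, and after the correction 0 did. The window at 1089 was −0.028 ± 0.36 (SD, n = 24) against −0.42 ± 0.18 (SD, n = 36), above the other group's mean in 20 of 24 sectors (permutation test, adjusted p = 1.2e-05). Among Cy3 sectors against YJL6032 these windows were −0.03 and −0.48 (permutation test, p = 1e-05). The window at 567 was −0.51 ± 0.53 (SD, n = 22) after re-replication at 1089, below the 0.53 of re-replication at 567, all 36 of whose sectors lay above that mean (permutation test, adjusted p = 1.2e-05). A single sector, sample 73 (YJL7140), stood at 1.75, on the sector array with the fewest values, 715. With arrays under 4000 placed features left out, the window after re-replication at 1089 was −0.61 ± 0.15 (SD, n = 17).

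Against controls, genes around 1089 were higher after re-replication there. ESC2, which acts in genome stability, was higher by 0.74 ± 0.09 (SE; limma, adjusted p = 4.44e-10) in 16 of 19 sectors, and RTT103, a transcription termination gene, by 0.60 ± 0.10 (adjusted p = 5.77e-06) in 13 of 15. UBX5 (0.72), FCF1 (0.73), the translation regulator gene SSD1 (0.69), the ATP synthase gene TIM11 (0.65, with a value in 5 sectors), glyoxalase GLO2 (0.62), NSE3 of the Smc5/6 complex (0.48) and the repressor gene SUM1 (0.46) rose too. All of these but NSE3 were named for lying in called gains on these arrays, so their rise is no independent evidence. Nearest to the locus, IPK1 passed (0.44, adjusted p = 0.0168; 9 of 16 sectors, with plain means of −0.23 and −0.15), whereas OMS1 (0.26), HIM1 (0.55) and MCM21 (0.24) did not. NPL3 (0.30) and TIF35 (0.30), farther right, passed in the fit against plain means of 0.12 and −0.013, below the 0.25 and 0.079 of controls, with 4 of 23 and 3 of 15 sectors above the control mean. GPI19 (0.24) did not pass. Of 20 tested replication and repair genes on the chromosome, NSE3, RTT103 and ESC2 were higher and none lower, also when adjusted over the list alone, and trend-corrected RAD30 (0.30) joined them. NSE3 did not pass with values not centred, with dye alone or without dye and reference terms, nor did IPK1 in the first 2 of these. Without dye and reference terms IPK1, NPL3 and TIF35 turned to lower. CDC6 (0.87 ± 0.13, 10 of 10 sectors, with a value in only 10 controls) and PDE1 (0.33) were higher off chromosome IV, and VPS53 fell by 0.31 and HGH1 by 0.46. Before centring, CDC6 had means of 0.17 at 1089 and −0.77 in controls, so here too the controls were low. TDA10 was fitted as higher by 0.48, in 11 of 21 sectors. HGH1 and TDA10 did not pass without dye and reference terms, and NPL3 and TIF35 did not with values not centred. Within 60 features of the locus 67 of 102 features were higher and 0 lower. In all 253 features were higher and 243 lower, against 123 and 449 with values not centred and 384 and 133 with trend-corrected values. No dye and reference combination was shared with the controls. CDC6 (−0.45), TDA10 (−0.63), NPL3 (−0.022) and TIF35 (−0.13) reversed with the labelled direction and HGH1 no longer passed, while OMS1, HIM1 and MCM21 came to pass, and 1344 features were higher and 1450 lower.

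**Figure D3:**
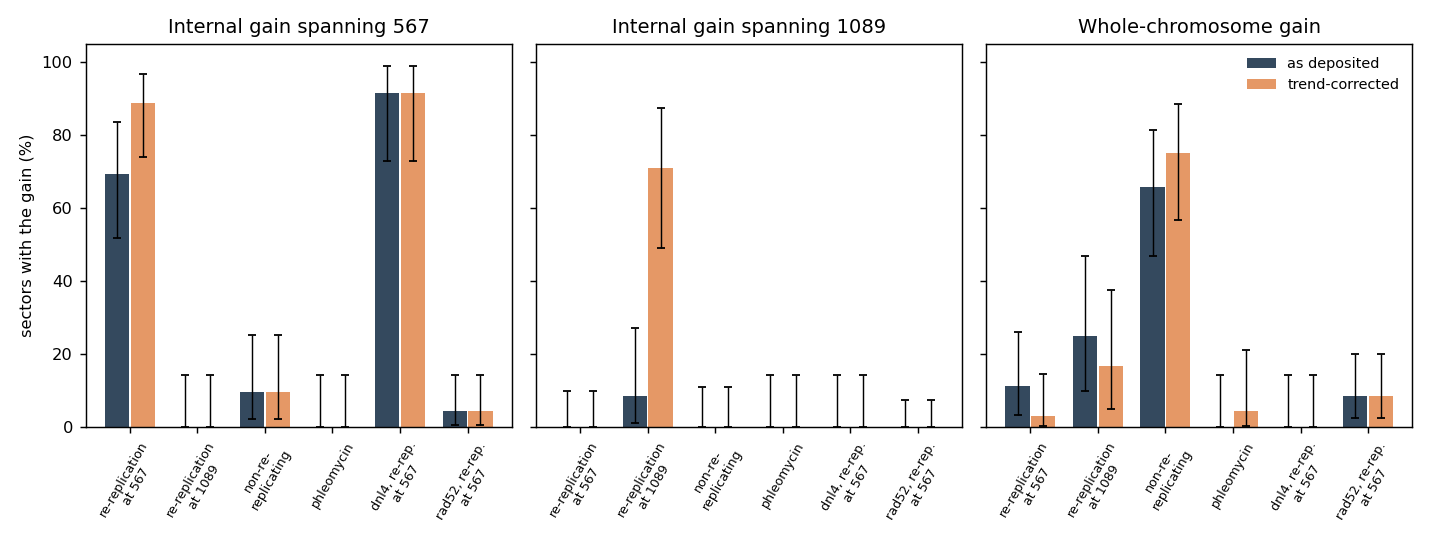
Percent of sectors in each group with an internal gain spanning 567, an internal gain spanning 1089 or a gain of a whole chromosome, for values as deposited and trend-corrected, with 95% Clopper-Pearson intervals as bars. Internal gains at 567 were called in 69.4% of sectors after re-replication there and in 4.17% of rad52 sectors, and gains at 1089 in 8.33% as deposited and 70.8% trend-corrected.

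Whole chromosomes were gained mainly by control sectors, in 21 of 32 (65.6%, 46.8 to 81.4%) against 4 of 36 after re-replication at 567 (Fisher's exact test, adjusted p = 7.70e-06). These are shares of the red sectors picked, and how often cells of each group gained a chromosome was not measured. Controls gained chromosome II in 9 sectors at a mean log2 of 0.89, V in 7 (0.90), XIII in 5 (0.88) and III in 3 (1.09), and I, VI and XVI in 1 sector each. Re-replication at 567 was accompanied by gains of I in 2 sectors and of III and V in 1 each. Trend-corrected values left only that of III, 1 of 36, against 24 of 32 controls, 4 of 24 at 1089 and 1 of 24 after phleomycin. After re-replication at 1089, 6 of 24 sectors gained a whole chromosome (adjusted p = 0.196), 0 of 24 after phleomycin and 0 of 24 in dnl4 (adjusted p = 0.191 each), and 4 of 48 in rad52 (adjusted p = 0.720), of which 3 gained XIII, which carries RAD52, and 1 gained II. Phleomycin sectors lost chromosome I in 2 cases and VIII in 1, and a control and a rad52 sector each lost I. Within single sets of dye and reference, the control gains were 21 of 32 against 1 of 9 (Fisher's exact test, p = 0.00643), and the others 6 of 24 against 3 of 25 (1089), 0 of 24 against 3 of 25 (phleomycin), 0 of 24 against 0 of 2 (dnl4), and 2 of 11 against 1 of 9 and 2 of 33 against 0 of 2 (rad52). The difference for 1089 passed at a gain threshold of 0.3 (14 of 24 against 7 of 36), at a penalty of 40 (12 against 4), centred on the mode (13 against 7) and on intergenic features (16 against 4), and that for dnl4 centred on the mode (0 of 24 against 7 of 36). The call of the controls ended under the labelled direction (1 of 32 against 3 of 36), where a gain reads as a loss in sectors labelled Cy5.

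Among the rad52 sectors picked, the gain around DBF4 was rare. It was called in 2 of 48 sectors (4.17%, 0.509 to 14.2%), against 25 of 36 in sectors of re-replication at 567 from strains not named for a mutation, called intact here (Fisher's exact test, adjusted p = 1.01e-09), and 31 of 48 had no gain or loss call. The window stood at 0.014 ± 0.18 (SD, n = 48) against 0.53 ± 0.40 (SD, n = 36), with 32 of 36 intact sectors above the rad52 mean (permutation test, adjusted p = 1.2e-05). DBF4 fell by 0.94 ± 0.13 (SE; limma, adjusted p = 1.36e-08) in 40 of 41 sectors and RAD55 by 1.08 ± 0.13 (adjusted p = 2.40e-11) in 39 of 39. VMS1 (−0.90), TPI1 (−0.95), DET1 (−0.97), CDC34 (−0.85), EMC10 (−0.86), PST1 (−0.51), SNF11 (−0.78), RSM10 (−0.59), BAP3 (−0.78) and the haem synthesis genes HEM13 (−0.90) and HEM12 (−0.75) were lower as well, PST1 not past the threshold with values not centred. Plain means, rad52 before intact, lay closer together than the fit for DBF4 (0.032 and 0.66) and RAD55 (−0.089 and 0.60). Among dye and reference sets, the gain was called in 0 of 11 rad52 against 8 of 9 intact Cy5 sectors (Fisher's exact test, p = 7.14e-05) and in 2 of 33 against 2 of 2 Cy3 sectors (p = 0.0101), with windows of 0.04 against 0.82 (exact permutation test, p = 5.95e-06) and 0.01 against 1.10 (exact permutation test, p = 0.00336). With the labelled direction the window difference was 0.13 and not past the threshold (adjusted p = 0.251).

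Elsewhere in rad52 sectors, the tryptophan synthesis gene TRP1, a common marker for gene replacement, was higher by 1.18 ± 0.09 (SE; limma, adjusted p = 6.01e-22) in 32 of 32 sectors, a sign that was itself used to choose the direction. HIS3 was higher by 0.27 ± 0.07 (adjusted p = 0.00127) in 38 of 44 and ASK10 by 0.36 in 33 of 33, whereas TDA10 fell by 0.63, OSW7 by 0.46 and UBP11 by 0.49. DNL4 was at 0.07 (adjusted p = 0.524). Of the marker genes TRP1 and HIS3 rose, and CAN1 (0.13) joined them adjusted over the list alone; trend-corrected, CAN1 (0.34) passed over all features and ADE2 was lower (−0.12) over the list alone. Of the chromosome IV replication and repair genes DBF4, CDC34 and RAD55 fell and none rose, also adjusted over the list alone, but trend-corrected MSH6 fell too (−0.72) and CDC13 rose (0.29), although that list's median differed by 0.027 (adjusted p = 0.441; 32 of 48 sectors above). In all 762 features were higher and 1059 lower of 11290, and within 60 features of the locus 82 of 102 were lower and 2 higher. Under the labelled direction 941 were higher and 748 lower, and all rad52 differences of single genes given here and above reversed except that of CAN1, which was not run, among them DBF4 (0.43, adjusted p = 0.039), RAD55 (0.29, adjusted p = 0.206), RAD52 (0.50, adjusted p = 0.0747) and TRP1 (−0.25, adjusted p = 0.199).

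In dnl4 sectors the gain around DBF4 was found in nearly every sector. It was called in 22 of 24 (91.7%, 73.0 to 99.0%) against 25 of 36, a difference of 22.2 percentage points that did not pass Fisher's exact test (adjusted p = 0.103), with a mean log2 of 0.72 ± 0.19 (SD, n = 22) and a median length of 82.5 features. The window stood higher, at 0.80 ± 0.32 (SD, n = 24) against 0.53 ± 0.40 (SD, n = 36), and 7 of the 36 intact sectors lay above the dnl4 mean (permutation test, adjusted p = 0.00835). That call ended with values not centred (adjusted p = 0.164) and trend-corrected (adjusted p = 0.147), and the share differed past the threshold at a gain threshold of 0.6 (9 of 36 against 15 of 24, adjusted p = 0.0181), on ORF features alone (23 of 36 against 22 of 24, adjusted p = 0.0311) and with the labelled direction (17 of 36 against 22 of 24, adjusted p = 0.000982). Trend-corrected values gave 32 of 36 against 22 of 24. Only 2 intact sectors shared the dye and reference of the dnl4 arrays, with the gain in 2 of 2 against 22 of 24 and windows of 1.10 and 0.80 (exact permutation test, p = 0.203).

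Feature by feature, the genes nearest to the locus did not pass the test in dnl4. Within 60 features of the locus 6 of 102 features were higher and 28 lower. DBF4 (0.055), CDC34 (0.14), VMS1 (−0.016), TPI1 (−0.036), DET1 (−0.19), PST1 (0.32), EMC10 (−0.068), TVP23 (0.31) and BAP3 (0.75) did not pass, whereas RSM10, a mitochondrial ribosome gene, was higher by 0.49 ± 0.16 (SE; limma, adjusted p = 0.0125) in 11 of 11 sectors. TRP1 was higher by 1.38 ± 0.10 (adjusted p = 6.87e-23) in 19 of 19 sectors, HIS3 by 0.41 in 21 of 21 and CAN1 by 0.32 in 10 of 11, while ADE2 was fitted as lower by 0.22 with plain means of −0.26 and −0.39. CDC13 of telomere capping (0.49), the polymerase gene POL3 (0.52; 5 sectors had a value) and RAD59 (0.43) were higher, and RAD61 was fitted as lower by 0.33 with plain means of −0.39 and −0.45; adjusted over the list alone, RAD61 did not pass, whereas trend-corrected it did and RTT103 (−0.21) was lower too. ZIP2 fell by 1.00, SDS22 by 1.06, RIF2 by 0.91, IPA1 by 0.77 and MMM1 by 0.50 in the fit. Their plain means, dnl4 before intact, lay closer together: ZIP2 (−0.30 and 0.068), SDS22 (−0.58 and −0.17), RIF2 (−0.26 and 0.045), IPA1 (−0.24 and 0.066) and MMM1 (−0.20 and −0.072). RAD52 was at 0.0014. The fit opposed the plain means, dnl4 before intact, also for VMS1 (0.90 and 0.71), TPI1 (1.00 and 0.74), DET1 (0.83 and 0.60), EMC10 (0.72 and 0.57) and RAD52 (0.073 and 0.16). In all 1812 features were higher and 2273 lower, against 552 and 3080 with values not centred, and 132 passed in the fit of these groups alone. There RSM10, RAD59, RAD61, HIS3, CAN1, ADE2, ZIP2, SDS22, RIF2 and IPA1 did not pass and POL3 reversed (−0.41), and with values not centred RSM10, RAD59, POL3 and CAN1 did not pass. Without reference terms, with or without dye, CDC13 did not pass and DBF4, PST1, TVP23 and BAP3 did, and RAD59 did not without both. In both of these settings VMS1, TPI1, DET1, EMC10, ADE2 and RAD61 turned to higher. TRP1 (0.058, adjusted p = 0.836), CDC13, POL3, RAD61, CAN1, ADE2 and MMM1 no longer passed with the labelled direction, HIS3, RAD59, ZIP2, SDS22, RIF2 and IPA1 reversed, and DBF4 (1.37), CDC34 (1.12) and VMS1 (1.10) were higher past the threshold.

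**Figure D4:**
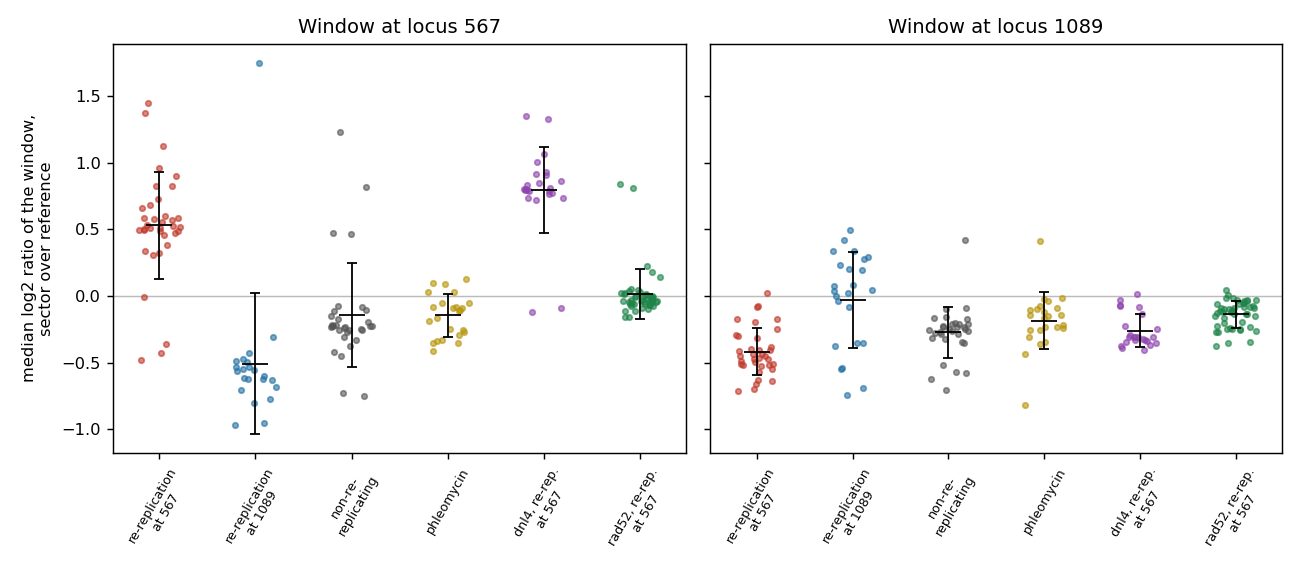
Median log2 ratio, sector over reference, of the features within 15 features of 567 or of 1089 on either side, for each sector (points), with the mean and SD of each group. At 567 the 36 sectors after re-replication there averaged 0.53 and the 24 dnl4 sectors 0.80, while controls, phleomycin and rad52 sectors averaged −0.14, −0.15 and 0.01.

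The gene lists fixed in advance moved by small amounts apart from the mitochondrial genome. In control sectors the mitochondrial genes had a mean list median of −0.50 (n = 32), against −1.61 (n = 21) after re-replication at 567 (difference −1.11, permutation test, adjusted p = 0.00194; 16 of 21 sectors below the control mean, but −0.15 among Cy5 sectors against YJL6558, 9 against 32, with 6 of 9 below, exact permutation test, adjusted p = 0.822), −1.85 (n = 11) after re-replication at 1089 (adjusted p = 8.18e-05; 11 of 11) and −1.44 (n = 24) after phleomycin (adjusted p = 0.000125; 23 of 24). In rad52 sectors it was −0.32 (n = 48), above the −1.61 of re-replication at 567 (adjusted p = 4.29e-05; 44 of 48), a difference that was −0.018 among Cy5 sectors against YJL6558. With the labelled direction the differences from controls were −1.56 at 567, −2.35 at 1089 and −1.94 after phleomycin. No single mitochondrial gene passed limma in these 4 comparisons, over all features or adjusted over the list alone, except that trend-corrected ATP6 was higher at 1089 (1.04) over the list alone, against the list's sign. Of the 7 members on the array 2 had enough values for limma at 1089 and 5 in the other comparisons, so these list medians depend on which members an array measured. In dnl4 the list differed by 0.24 (adjusted p = 0.589), of opposite sign to its members ATP6 (−1.03), VAR1 (−1.51) and COX3 (−1.22), which passed limma over all features and adjusted over the list alone, though VAR1 and COX3 did not with the labelled direction, COX3 did not with dye alone and none of the 3 did in the fit of these groups alone. The plain means opposed the fit for ATP6 (−1.27 in dnl4, −1.59 in intact sectors) and COX3 (−0.82 and −0.85).

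Licensing genes (MCM7, CDC6, ORC2, ORC6) had lower medians than controls after re-replication at 567 (−0.28, adjusted p = 3.00e-04; 34 of 36 sectors), at 1089 (−0.35, adjusted p = 0.000686; 22 of 23) and phleomycin (−0.36, adjusted p = 6e-05; 24 of 24), and higher ones than re-replication at 567 in rad52 (0.15, adjusted p = 4.29e-05; 47 of 48) and dnl4 (0.15, adjusted p = 0.00086; 22 of 24). The 3 differences from controls turned with the labelled direction, to 0.12, 0.072 and 0.060 (adjusted p = 0.145, 0.567 and 0.576), and among Cy5 sectors against YJL6558 that at 567 was −0.18 (7 of 9 sectors; exact permutation test, adjusted p = 0.311). The call in dnl4 ended with values not centred (0.037, adjusted p = 0.660). List tests had no covariates, and neither 1089 nor phleomycin shared a dye and reference set with controls. The members of this list went both ways in limma. CDC6 was higher, against low values in controls, and ORC2 lower, by 0.26 and 0.50, after re-replication at 567 and 1089, both reversed with the labelled direction. At 567 ORC2 did not pass with values not centred, in the fit of these groups alone or with Cy5 sectors against YJL6558. MCM7 joined the lower genes at 567 adjusted over the list alone, and none passed in the other 3 comparisons. Recombination and end-joining genes had lower medians at 567 (−0.19; 34 of 36), 1089 (−0.30; 21 of 23) and after phleomycin (−0.14; 24 of 24), with adjusted p of 4.29e-05, 4.29e-05 and 0.00263, and a higher one in rad52 (0.15, adjusted p = 4.29e-05; 42 of 48), but not in dnl4 (0.090, adjusted p = 0.0717; 16 of 23). The calls at 567 (−0.11, adjusted p = 0.0553) and in rad52 (0.050, adjusted p = 0.344) ended with the labelled direction, and that at 1089 with trend-corrected values (−0.093, adjusted p = 0.0823), with which the list in rad52 stood at 0.081 and dnl4 came to pass (0.081, adjusted p = 0.0171). Over all features or adjusted over the list alone, NEJ1 fell by 0.39 after re-replication at 1089, and LIF1 rose after phleomycin against the list's sign. Neither call held trend-corrected (NEJ1 −0.17, adjusted p = 0.341; LIF1 0.11, adjusted p = 0.348), and NEJ1 stood at 0.014 with the labelled direction. Trend-corrected, NEJ1 was instead lower at 567 (−0.24) and after phleomycin (−0.29), and LIF1 in dnl4 (−0.19), the last over all features alone.

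Strain marker genes had lower medians than controls at 567 (−0.098, adjusted p = 0.0015; 33 of 36) and after phleomycin (−0.22, adjusted p = 4.29e-05; 23 of 23), not at 1089 (−0.062, adjusted p = 0.864; 22 of 24), and higher ones than re-replication at 567 in rad52 (0.065, adjusted p = 0.00994; 38 of 48) and dnl4 (0.15, adjusted p = 6e-05; 21 of 24). TRP1, a basis of the direction, is a member. The list reversed with the labelled direction at 567 (0.050, adjusted p = 0.123) and 1089 (0.13, adjusted p = 0.428), and did not pass after phleomycin (−0.025, adjusted p = 0.488) or in rad52 (0.028, adjusted p = 0.394). With values not centred it passed at 1089 (−0.20, adjusted p = 0.0428; 23 of 24) and in rad52 at 0.11, but not in dnl4 (0.038, adjusted p = 0.699). Trend-corrected it was 0.12 in rad52, and among Cy5 sectors against YJL6558 −0.0077 at 567. After phleomycin ADE2 rose in the fit and URA3 and LEU2 fell, and in dnl4 3 rose and 1 fell, alike adjusted over the list alone. Trend-corrected, the ADE2 and LEU2 calls after phleomycin ended, CAN1 was higher there (0.38) and at 1089 CAN1 was lower (−0.32). The pair of targeted genes had a lower median at 567 (−0.18, adjusted p = 6e-05; 33 of 35) and at 1089 (−0.26, adjusted p = 4.29e-05; 16 of 19), and differed by 0.040 after phleomycin (adjusted p = 0.515; 12 of 21). These differences were 0.017 (adjusted p = 0.725), −0.060 (adjusted p = 0.408) and 0.24 (adjusted p = 5e-05) with the labelled direction, and trend-corrected that at 1089 was −0.14. In rad52 and dnl4 the missing values of RAD52 or DNL4 set this median, so its difference says nothing there. Beyond RAD52 in rad52 and DNL4 after phleomycin, no targeted gene passed limma, over all features or adjusted over the list alone, while trend-corrected DNL4 passed there over the list alone. Without reference terms, with or without dye, DNL4 also passed at 567 (−0.12 and −0.13), 1089 (−0.29 and −0.30) and in rad52 (0.22 each), and RAD52 passed at 567 (−0.20) and 1089 (−0.26) without both, and with the labelled direction at 567 (0.52), after phleomycin (0.64) and in dnl4 (1.65). Medians of the chromosome IV replication and repair list did not pass at 1089 (0.057, adjusted p = 0.611; 12 of 24), after phleomycin (−0.035, adjusted p = 0.515; 12 of 24) or in dnl4 (0.093, adjusted p = 0.100; 16 of 24); with the labelled direction they passed as lower at 1089 (−0.24, adjusted p = 0.00496) and after phleomycin (−0.34, adjusted p = 5e-05). Trend-corrected, they passed as higher at 1089 (0.18, adjusted p = 0.0353; 12 of 24) and as lower after phleomycin (−0.080, adjusted p = 0.0139; 19 of 24), and with values not centred the list passed as higher in rad52 (0.071, adjusted p = 0.0428; 37 of 48). Within Cy5 sectors against YJL6558, 0 lists passed for re-replication at 567 against controls or for rad52.

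Gains over a locus ended at few places. At 567, left ends lay most often at CPP3 (10 and 6 of 25 at its 2 features) and ARO3 (8), an aromatic amino acid synthesis gene, and right ends at GRX3 (12), a glutaredoxin gene, MSH6 (6) and GIS1 (4). In dnl4, left ends lay at ARO3 (11 of 22) and CPP3 (6 and 2), and right ends at GRX3 (15). The 3 control gains began at CPP3 and ended at MSH6, CPP2 and YDR261W-A. At 1089, both gains called on deposited values began at YDR262W and ended at ESF1, as did 11 and 10 of 17 trend-corrected gains.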

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

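All tests in this part were chosen only after the result was seen, except that of the template beside centromeres. Repeat arrays of 9 sectors entered comparisons only where all arrays of a sector were averaged, and most carried a gain. Control sectors had no repeat arrays; on their single arrays 3 of 32 had a gain spanning 567. Of 7 repeat arrays after re-replication at 567, 6 had an internal gain spanning the locus, with a mean log2 of 1.05 ± 0.25 (SD), and of those after re-replication at 1089, 2 of 2 did, with a mean of 0.92 ± 0.02 (SD).

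Sector arrays carried a trend from the ends to the middle of chromosomes, with a slope on the template of 2.22 to 3.28 on 6 arrays whose repeat arrays, of the same sector, dye and reference, had slopes of −0.013 to 0.082. The median difference was 2.54 in these 6 sectors, which argues against the reference strain or dye orientation, and 2.38 over all 9, which argues against the genome of the sector or its group. Unequal replication of the 2 cultures stays open, because the template differed beside centromeres by −0.022 ± 0.057 (SD, 16 chromosomes, 9 lower; permutation test, p = 0.150). How the hybridisations of the sector and repeat arrays differed was not tested.

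Gains spanning 1089 rose from 2 to 17 of 24 sectors when the trend was removed. The correction itself gave such a gain in 0 of the 60 sectors of re-replication at 567 and dnl4, which were not in its template, although 15 of them had slopes as steep as the least steep sector at 1089. The median slope of those 15 was 2.43 (highest 3.19), against 3.17 (highest 3.79) at 1089. They were thus corrected less than most sectors at 1089. The explanation that the trend hides gains that are there predicted more equal calls on the 2 arrays of a sector, and these rose from 6 to 9 of 9. Only 2 of these sectors, YJL7120 and YJL7126, were of re-replication at 1089, and both came to equal calls. The other call that changed, YJL7110, was at 567. In simulations with the trend, gains at 1089 were called in 21 of 24 sectors at log2 1 and in 0 of 24 at 0.6. Mean gains there lay between, at 0.71 trend-corrected and 0.92 on the repeat arrays. Gains at 1089 hidden by the trend are a candidate explanation, found and tested on the same data.

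Off chromosome IV, 858 features passed the threshold for re-replication at 567 against control. Splitting the re-replicating sectors alone by dye and reference set (9 against 25) gave 3480, so that this set may account for many of the 858, although the fit had both as covariates. Whole-chromosome gains of the control sectors may account for lower features, since 72.9% of the 516 lower features lay on chromosomes II, V and XIII, which held 17.6% of those tested. No share could be assigned to either.

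Of 60 splits of the same arrays, the real one included, 1 gave as many features as re-replication at 567 against control (1012, highest other 626). The number was 2 for re-replication at 1089 (496, highest other 1065), 1 for phleomycin (3571, highest other 217), 1 for rad52 (1821, highest other 1) and 1 for dnl4 (4085, highest other 510). For the 4 comparisons other than 1089, the real split gave the most features. With 60 splits the share cannot fall below 1 of 60. Shuffled splits also lose the tie of group to dye and reference, so they exclude neither that tie nor chance. For 1089 the share was under 0.05, but another split gave more features than the real one, and what set that split apart was not tested.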

How the results depend on the processing

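The tests of the labelled direction, trend correction and arrays with few features were chosen only after the result was seen. Of 29 comparison results, 8 stayed the same under every alternative run. For tests this meant the same direction and side of the threshold. For counts of features or lists it meant a limited ratio to the main count. For profile heights it meant a change below the spread of smoothed values off chromosome IV. Of 291 comparison values 243 stayed the same in these respects, 12 came to pass the threshold, 6 no longer did, 21 counts or heights moved and 9 reversed. Of 731 values of named genes 509 stayed, 83 no longer passed, 27 came to pass and 112 reversed, and of 102 list values 60, 21, 7 and 14. Except where the setting itself tells (fewer sectors, or a turned sign), the cause was not tested. Missing values, in place of signal over background, limit the arrays.

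Shares are differences in percentage points. At a gain threshold of 0.6, internal gains at 567 differed by 18.8 from control (adjusted p = 0.0904) and −37.5 from dnl4 (adjusted p = 0.0181), and whole-chromosome gains of rad52 by 0.694. At a threshold of 0.3 and at a penalty of 40, whole-chromosome gains at 1089 differed by 38.9 each. Centred on the mode, the differences were 25.0 for gains at 1089, 34.7 for whole chromosomes at 1089 and −19.4 for dnl4. With the mean over all arrays of a sector, which could alter only 2 sectors at 1089, gains at 1089 differed by 16.7. On ORF features alone dnl4 gave −27.8 for gains at 567 and 6.94 for whole chromosomes, and on intergenic features whole chromosomes at 1089 gave 55.6. Both trend corrections gave 70.8 for gains at 1089, and 1.39 for phleomycin and 5.56 for rad52 in whole chromosomes. With the labelled direction, gains at 567 differed by 25.3 from control and −44.4 from dnl4, and control whole-chromosome gains by −5.21. With Cy5 against YJL6558 alone, rad52 whole chromosomes gave 7.07.

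With the labelled direction the windows at 567 differed by −0.021 (control), 0.27 (phleomycin) and 0.13 (rad52). For dnl4 the window differed by −0.15 not centred and −0.14 trend-corrected. The 567 profile peak was 0.59 with a running median of 41.

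Features past the threshold without dye or reference numbered 4447 (567), 5835 (1089), 5926 (phleomycin) and 5983 (rad52), and with dye alone 4075 (567), 4471 (1089) and 6073 (rad52). With only the groups compared they were 172 (567) and 132 (dnl4), with Cy5 against YJL6558 137 (567), not centred 498 (567) and 1058 (rad52), trend-corrected 1686 (phleomycin), and with the labelled direction 2794 (1089) and 1819 (dnl4). Lists past the threshold were 0 for Cy5 against YJL6558 (567 and rad52) 0 for dnl4 not centred, and with the labelled direction 2 each for 567 and rad52. The chromosome IV list reversed for values not centred at 1089 (−0.078) and dnl4 (−0.021) and trend-corrected for rad52 (−0.0087), the recombination list for dnl4 not centred (−0.030), and the mitochondrial list for rad52 with Cy5 against YJL6558 (−0.018). The labelled direction reversed the chromosome IV list at 567 (−0.23) and 1089 (−0.24), the licensing list at 567 (0.12), 1089 (0.072) and after phleomycin (0.060), the marker list at 567 (0.050) and 1089 (0.13), the targeted genes at 567 (0.017) and the mitochondrial list in dnl4 (−0.31).

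Reversed genes without dye or reference were, at 1089, IPK1 (−0.081), NPL3 (−0.13) and TIF35 (−0.092), and after phleomycin TPI1 (−0.27), DET1 (−0.10), EMC10 (−0.034), PSF1 (−0.064), RTT103 (−0.0024), RAD30 (−0.099), ADE2 (−0.17) and VHT1 (−0.046). In dnl4 they were RAD52 (−0.091), VMS1 (0.19), TPI1 (0.26), DET1 (0.23), EMC10 (0.14), RAD61 (0.061), ADE2 (0.13), ATP6 (0.32) and COX3 (0.028). With dye alone they were MCM21 at 1089 (−0.17), TPI1 (−0.24) and ADE2 (−0.013) after phleomycin, and in dnl4 RAD52 (−0.078), VMS1 (0.24), TPI1 (0.28), DET1 (0.28), EMC10 (0.28), RAD61 (0.016), ADE2 (0.18) and ATP6 (0.56). With values not centred DNL4 at 567 (0.012), RAD52 after phleomycin (0.064) and, in dnl4, RAD52 (−0.12), DBF4 (−0.027) and CDC34 (−0.0034) reversed. With only the groups compared, DBF4 (−0.47), CDC34 (−0.10), TVP23 (−0.31) and POL3 (−0.41) in dnl4 did, and trend-corrected TPI1 after phleomycin (−0.051).

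Of 124 values of named genes 71, and of 30 of lists 9, reversed with the labelled direction. The reversed genes were, at 567, RAD52 (0.52), DNL4 (0.069), DBF4 (−0.88), CDC34 (−0.64), RAD55 (−0.81), MSH6 (−0.67), VMS1 (−0.81), TPI1 (−0.53), DET1 (−0.56), PST1 (−0.72), EMC10 (−0.93), SNF11 (−0.39), HEM12 (−0.61), BAP3 (−0.87), YOS9 (−0.75), TVP23 (−0.71), FMP16 (−0.73), TDA10 (−0.44), CDC6 (−0.65), SEF1 (−0.52), YCH1 (−0.44), CHK1 (0.62) and ORC2 (0.24). At 1089 they were RAD52 (0.47), NPL3 (−0.022), TIF35 (−0.13), CDC6 (−0.45), ORC2 (0.0080), TDA10 (−0.63) and NEJ1 (0.014), after phleomycin RAD52 (0.64), DBF4 (−1.45), CDC34 (−1.38), VMS1 (−1.38), TPI1 (−1.32), DET1 (−1.10), PST1 (−0.91), EMC10 (−1.47), RAD55 (−1.43) and YNL143C (−0.025), and in rad52 RAD52 (0.50), DNL4 (−0.13), DBF4 (0.43), CDC34 (0.21), RAD55 (0.29), VMS1 (0.30), TPI1 (0.22), DET1 (0.21), PST1 (0.51), EMC10 (0.35), HEM13 (0.26), SNF11 (0.039), HEM12 (0.041), RSM10 (0.27), BAP3 (0.21), TRP1 (−0.25), HIS3 (−0.27), TDA10 (0.23), ASK10 (−0.26), OSW7 (0.44) and UBP11 (0.39). In dnl4 they were VMS1 (1.10), TPI1 (1.06), DET1 (0.92), EMC10 (1.10), RAD59 (−0.11), HIS3 (−0.12), ZIP2 (0.13), SDS22 (0.051), RIF2 (0.20) and IPA1 (0.25).

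Not run were features with a value on every array (0 features), the groups compared alone for 1089 and phleomycin, which could not be fitted with dye and reference, Cy5 sectors where a group had none, and ends at annotated transposable elements with their distances. No paired analysis was possible because the groups share no sample numbers in the labels.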

Other observations

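All tests in this part were chosen only after the result was seen. The RefSeq gene table holds 8 places on chromosome IV where a long gene and a short one are nested as in a Ty retrotransposon, a mobile element found in many copies, and ends of gains lay near them. After trend correction, left ends at 567 lay within 6 features of such a pair in 21 of 32 gains and right ends in 30 of 32, at YDR034C-D and YDR098C-B for 21 and 28. At 1089 the counts were 13 of 17 at YDR261C-D and 10 of 17 at YDR365W-B. Ends shared by many sectors are not independent, so all ends of a side were moved together along it. These shifts gave 0.738, 2.33, 0.976 and 0.804 ends on average, and as many as observed in 12 of 564 (p = 0.0213), 3 of 922 (p = 0.00325), 51 of 1063 (p = 0.048) and 18 of 423 (p = 0.0426). Within 2 features the left ends at 567 gave 0 of 32 (p = 1), so that distance matters there. These counts are consistent with repeated elements at the ends of gains, a hypothesis that the gene pairs, which are not annotated here as elements, cannot settle.

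In dnl4 sectors, 9 of 22 left ends and 19 of 22 right ends lay within 6 features of a pair on deposited values. The 3 control gains shared the left pair YDR034C-D and had right ends at YDR098C-B, YDR210W-B and YDR261W-B. Of the 2 rad52 gains, 1 had a left end near a pair on deposited values and 2 after trend correction, and 0 had a right end near one in either, their right ends lying at SNF11 and PET100.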
